A study of Mus musculus with 6 samples.

How the data were processed

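Total RNA of asynchronous KEC cells, a mouse kidney epithelial line grown in serum-containing medium, was extracted with TRIzol and made into libraries with a stranded mRNA kit, per the labels' protocols. Each of the 6 libraries has its own table of 43432 genes. Reads were processed with STAR 2.7.6 and RSEM 1.3.1 against the mouse genome build mm10, per the submitters' processing notes. The transcript annotation and the strand setting used for counting are not given in the sources used here.

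Expected counts, per the file headers, are the estimated reads per gene that RSEM gives before normalization, with reads that match several genes shared in fractions. TPM values, per the file headers, are transcript abundances scaled for length and depth, which RSEM derives from expected counts and effective lengths. Effective lengths, per the file headers, are in bases and weighted by the isoforms found in each library, another kind of value that was used only as an offset and for Hnf1b. No column was pooled over libraries, and 0 columns of per-sample values were left unused.

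Samples were grouped by genotype from the titles, 3 WT and 3 HNF1B_KO. Expected counts were rounded to whole numbers and tested with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr (minimum count 10, minimum total count 15), which left 14593 genes that hold at least 99.9% of the counts of every library. Library sizes were scaled with TMM, and HNF1B_KO was compared with WT by the quasi-likelihood F test (glmQLFit and glmQLFTest) with Benjamini-Hochberg adjustment over all tested genes and a threshold of 0.05. CPM values use the TMM-scaled library sizes. The standard error of a log2 fold change was taken as its size divided by the square root of the F statistic. Depth ranged from 33054090 to 40443956 expected counts per library, so that 3 counts over the 3 libraries of a group correspond to 0.0282 CPM in HNF1B_KO and 0.0266 CPM in WT. That floor was used for every fold against a group at 0 counts. Genes named by rule with 1 to 3 counts in a group are given as a ratio of counts with a 95% interval.

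Gene symbols and coordinates came from GENCODE M21, which is on the same build. A symbol was found for 42462 gene IDs and none for 970. Among the 70 genes named by rule, 21 share at least 1 exon base with another annotated gene and 3 of these over 20% of their exon bases, and 14 had a fractional count in at least 1 library. Without the strand setting, reads of such overlapping genes cannot be told apart, and the levels of these genes are uncertain to that extent. Whether a count was whole was judged with a tolerance of 0.005.

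The test, the groups, 20 gene lists, the rule for named genes and the alternatives, except where stated, were fixed before the data were examined. The named genes are Hnf1b; the 6 largest rises and 6 largest falls in fitted log2 fold change among changed genes with no overlap of the groups and a mean of at least 5 CPM, leaving out clone, model and pseudogene names; of each list, among changed members, the 2 with the smallest p in the commoner direction and the 1 with the smallest p in the other; and Top1 with the most abundant member of the topoisomerase list and of each list of another cell type. Other members are given as examples of their list and were chosen after their values were seen. The lists cover HNF1B targets, cystic disease and cilium genes, kidney transcription factors, proximal tubule, distal nephron and collecting duct, epithelial junctions and polarity, mesenchymal transition and matrix, mitosis, DNA replication, cholesterol synthesis, canonical WNT pathway, Notch pathway, interferon response, p53 targets, topoisomerases, oxidative phosphorylation, and markers of fibroblasts, leukocytes, endothelium and podocytes. Lists were tested with camera at a preset correlation of 0.01 with Benjamini-Hochberg adjustment over the 20 lists, and again with an estimated correlation and with fry (limma 3.58.1). A further 6 lists, of genes of the 2-cell stage, pluripotency, imprinting, the germline, HOX clusters and fatty acid synthesis, were chosen after the data had been seen and were adjusted over those 6.

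Positional context was the median log2 fold change of the 50 nearest tested genes on the chromosome, for 14444 genes. Measures of whole libraries were compared with two-sided exact permutation tests.

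The alternatives were other scalings (DESeq2 size factors, library totals, upper quartile), no filter or a mean count of at least 50, the DESeq2 1.42.0 Wald test, limma voom, glmTreat against a fold of 1.2, a robust fit, offsets from effective lengths, and limma on log2 TPM with a pseudocount of 1 or 0.1. The replicate number as a block, an adjusted p under 0.01 and leaving out each library in turn were also tried. Removal of trends over GC content and length was added after the data had been seen.

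The scripts were tested on simulated data. For HNF1B_KO against WT, with 14417 genes and 50 changed at each size, edgeR called 30% of 1.25-fold, 62% of 1.5-fold, 88% of 2-fold and 100% of 4-fold changes, and 4.76% of calls were false. With 14402 genes and the cholesterol synthesis list lowered by 0.5 on the log2 scale, camera called 1 of 20 lists, the lowered one. The simulated genes varied independently, so this does not show how often lists of correlated genes are called falsely. With simulated changes at the positions of 14444 genes, 100% of scattered changes and 2.5% of changes in a block still differed 2-fold from their window. In the same simulation the nearest expressed neighbour was lost for 100% of genes lost in the block and 1% of genes lost singly. The simulated block was longer than the window, and only genes away from its ends were compared with their window. Shorter blocks, block edges and small deletions were not tried.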

Results

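RNA from KEC, a mouse kidney epithelial cell line, was sequenced in 6 libraries from asynchronous cultures. There were 3 libraries of wild-type cells (WT, replicates 1 to 3) and 3 of cells in which the gene for HNF1B had been targeted with CRISPR/Cas9 (HNF1B_KO, replicates 1 to 3). Expected counts summed to 40443956, 36095129 and 37836572 in the WT libraries and to 36441665, 35574814 and 33054090 in the HNF1B_KO libraries. HNF1B is a homeodomain transcription factor of the developing and adult renal epithelium, and it has been described as a factor that stays on mitotic chromosomes. The design compares the transcripts of cells with and without this targeting. The labels do not say whether the HNF1B_KO libraries come from 1 edited clone, several clones or a pool. Effects of HNF1B loss therefore cannot be separated from differences between clones in any of the results. Nothing in the labels says that replicates were separate cultures, so the p-values measure only the spread between these samples, which can be technical. Counting intervals and floors given for genes with few counts cover counting error only, because reads amplified by PCR are not independent molecules.

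The targeted gene, Hnf1b (ENSMUSG00000020679, mm10 chromosome 11, 83850063 to 83905819, plus strand, protein coding in GENCODE M21), was lower in every HNF1B_KO library than in every WT library. Its expected counts were 3020, 3363 and 3166 in WT replicates 1 to 3 and 1578, 1782 and 1333 in HNF1B_KO replicates 1 to 3. The normalised level was 84.9 ± 8.92 CPM (counts scaled to library size, mean ± SD, n = 3) in WT and 44.1 ± 5.05 CPM (SD, n = 3) in HNF1B_KO. Hnf1b fell by 0.94 on the log2 scale (SE 0.10, adjusted p = 5.4e-05, edgeR quasi-likelihood F test with Benjamini-Hochberg adjustment). A lesion made by Cas9 can leave the transcript in place, so the residual level measures the mRNA and not the protein. The effective length assigned to Hnf1b, which depends on the mix of isoforms, ranged from 2411 to 2495 bases in WT and from 2009 to 2196 bases in HNF1B_KO.

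**Figure D1:**
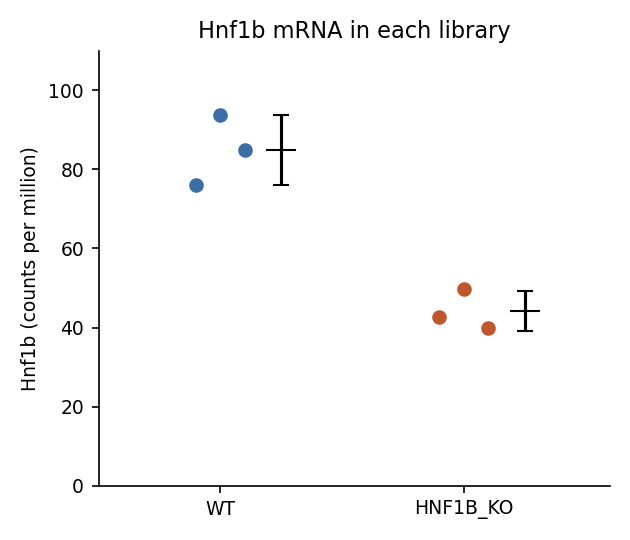
Hnf1b level in CPM (y axis) in each of the 3 WT and 3 HNF1B_KO libraries (points), with the group mean and SD as bars. The WT libraries lie between 75.97 and 93.80 CPM and the HNF1B_KO libraries between 39.91 and 49.70 CPM.

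Against WT, the HNF1B_KO cells had lost most of the RNA of several kidney genes, among them Pkhd1, the gene of recessive polycystic kidney disease, and Cdh16, which encodes kidney-specific cadherin. Of 26 genes of cholesterol synthesis 23 fell and 0 rose, and of 23 tested genes of the interferon response 17 rose and 3 fell. Both lists passed camera at its preset correlation but not with an estimated one, where for each the adjusted p = 0.235 with an estimated correlation. Of 14593 genes tested, 7580 changed (51.9%), 3663 upwards and 3917 downwards, at an adjusted p under 0.05 in the edgeR quasi-likelihood F test with Benjamini-Hochberg adjustment. Which direction held more genes depended on the processing, with 3997 upwards and 3545 downwards when scaled by library totals and 3811 and 3095 on log2(TPM + 1). Of the 7580 genes 1961 changed at least 2-fold, 1080 upwards and 881 downwards, and 458 changed at least 8-fold, 225 upwards and 233 downwards. The remaining changes were small for the most part, with 4067 of the 7580 under 1.5-fold. In 8860 tested genes (60.7%) the 3 libraries of one genotype all lay above the 3 of the other, where chance gives 10%. The first principal component held 84.5% of the variance and separated the genotypes. Common biological variation between replicates was 9.26%. Each changed gene named in the account of this comparison had the 3 libraries of one genotype all above the 3 of the other, except Kdr.

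The 6 largest rises among genes with a mean of at least 5 CPM, leaving out clone, model and pseudogene names, included Pik3c2g, a class II phosphoinositide 3-kinase, and Cyp3a13, a cytochrome P450 of xenobiotic metabolism. Pik3c2g had 2 counts over the 3 WT libraries together and 21.3 ± 0.730 CPM (SD, n = 3) in HNF1B_KO, a ratio of 1204 with a 95% counting interval of 333 to 9949. Cyp3a13 rose from 0.200 ± 0.114 to 11.2 ± 2.06 CPM. Spta1, the erythroid alpha spectrin, rose from 2.94 ± 0.926 to 70.8 ± 2.84 CPM, a log2 change of 4.58 (SE 0.16). Megf6 (log2 change 4.79, SE 0.30) and Col4a4, a basement membrane collagen chain (log2 change 4.09, SE 0.25), completed the group together with Zscan4f. Zscan4f, a gene of the mouse 2-cell embryo, rose by 4.97 on the log2 scale (SE 0.19), to 10.1 ± 1.3 CPM. Its counts were partly fractional because near-identical family members share reads, so its level is uncertain. Adjusted p for these 6 genes ran from 4.2e-08 for Pik3c2g to 2.6e-06 for Megf6 (edgeR quasi-likelihood F test with Benjamini-Hochberg adjustment).

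Under the same restrictions the 6 largest falls were Gnai1, Sult1c2, Slc36a4, Lox, ccdc198 and Ago1. Gnai1, an inhibitory G protein alpha subunit, stood at 32.5 ± 2.40 CPM (SD, n = 3) in WT and at 0 counts in all 3 HNF1B_KO libraries, at least 1153-fold lower when set against a floor of 3 counts over the 3 libraries together (0.0282 CPM). Sult1c2, a cytosolic sulfotransferase, stood at 26.3 ± 3.73 CPM in WT and at 0 counts in HNF1B_KO, at least 931-fold lower. Slc36a4, an amino acid transporter, had 12.1 ± 0.386 CPM in WT and 2 counts over the 3 HNF1B_KO libraries, a WT to HNF1B_KO ratio of 644 (95% counting interval 178 to 5320). Lox, the lysyl oxidase that cross-links collagen and elastin, fell from 428 ± 58.7 to 1.56 ± 0.155 CPM. Ccdc198, given as ccdc198 in the gene table, fell by 7.89 on the log2 scale (SE 0.32). Ago1, an Argonaute protein of RNA silencing, fell by 7.72 (SE 0.17), with fractional counts in at least 1 library. Adjusted p for the 6 genes ran from 1.4e-09 for Lox to 3.5e-07 for Sult1c2 (edgeR quasi-likelihood F test with Benjamini-Hochberg adjustment).

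**Figure D2:**
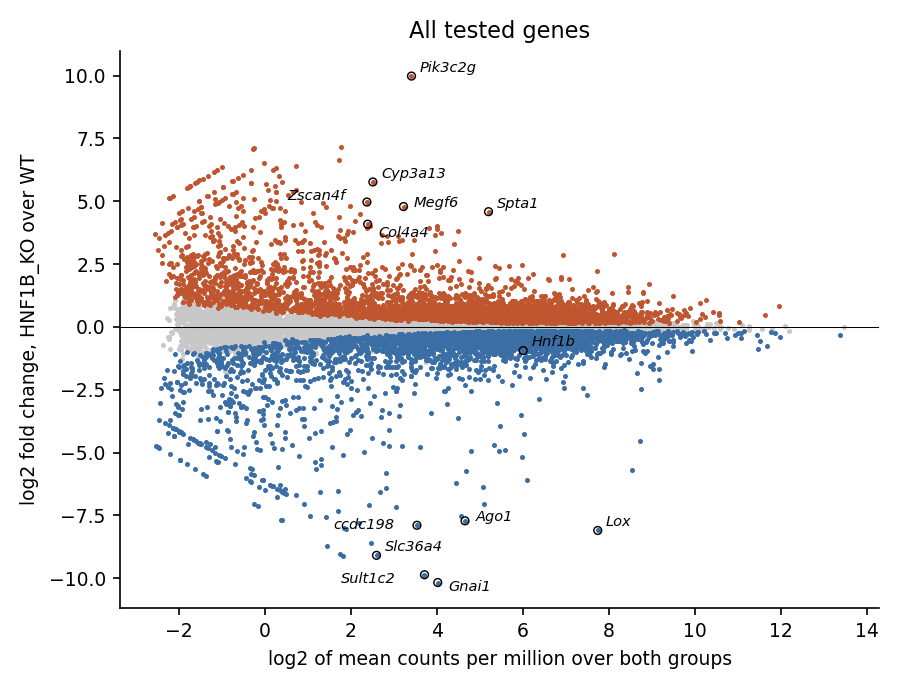
Log2 fold change of HNF1B_KO over WT (y axis) against mean level in log2 CPM (x axis) for the 14593 tested genes, with risen genes in orange, fallen genes in blue, genes not past the threshold in grey and circled genes named. Genes with 0 counts in a whole group are drawn at the lower bound of their change, as for Gnai1 at a fold of 1153, and genes with few counts at their fitted value.

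Known HNF1B targets fell as a group. Of 32 targets on the list fixed in advance, 21 were expressed highly enough to test: 16 fell, 1 rose and 4 did not pass, and the counts were 16 and 1 when adjusted over the list alone. Pkhd1 fell from 66.7 ± 0.628 to 0.812 ± 0.10 CPM (SD, n = 3 each), 82.0-fold lower, with a log2 change of -6.36 (SE 0.10, adjusted p = 1.2e-09, edgeR quasi-likelihood F test with Benjamini-Hochberg adjustment). Cdh16 fell from 729 ± 75.9 to 14.1 ± 3.83 CPM, 51.6-fold lower. Pde4c, a cyclic AMP phosphodiesterase, fell by 5.80 on the log2 scale, the potassium channel gene Kcnj16 by 4.10, and Pax2, a transcription factor of nephron development, by 1.59. Kif12, a kinesin gene, had 0 counts in HNF1B_KO against 0.605 CPM in WT, at least 21.4-fold lower. The gene that rose was Lfng, a glycosyltransferase that modifies Notch receptors, at a log2 change of 0.55 (SE 0.09), in a chromosomal window whose 50 nearest tested genes had a median log2 change of 0.35. Nphp1, Emx2, Glis2 and Slc3a1 did not pass, with log2 changes of 0.13, -0.14, -0.09 and 0.20. The median log2 change of the tested members was -1.59. In camera, which compares a list with all other genes at a preset correlation of 0.01, the list was lower with an adjusted p of 4.1e-19 (Benjamini-Hochberg over 20 lists), and the adjusted p = 0.0502 with an estimated correlation.

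**Figure D3:**
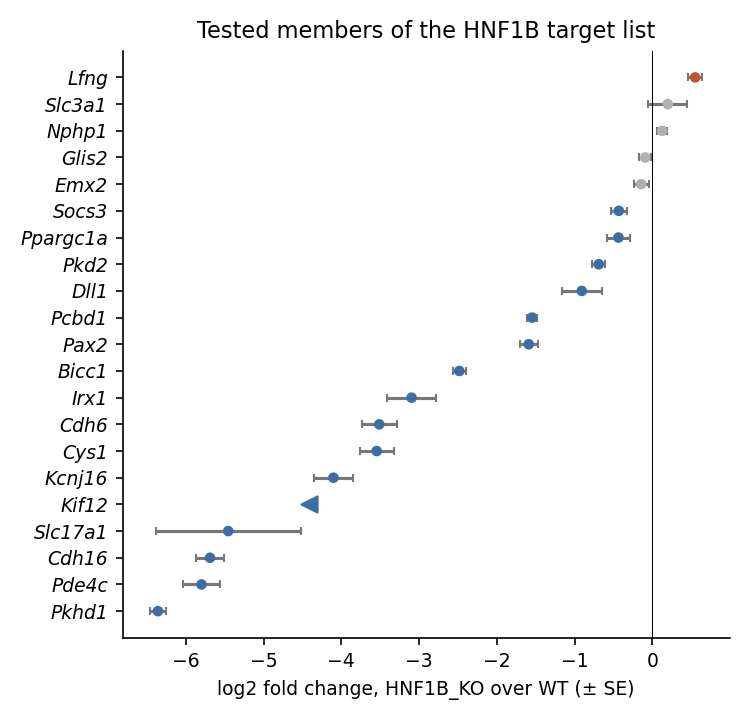
Log2 fold change of HNF1B_KO over WT (x axis) with its standard error for the 21 tested HNF1B targets (y axis), blue for genes that fell, orange for Lfng, which rose, and grey for the 4 not past the threshold. Kif12, with 0 counts in HNF1B_KO, is the triangle at its bound of 21.4-fold, Slc17a1, with 1 count there, is at its fitted value, and Pkhd1 lies at -6.36.

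Genes of cystic kidney disease and of the primary cilium were lower for the most part. All 36 members were tested: 20 fell, 2 rose and 14 did not pass, against 23 and 2 when adjusted over the list alone. Pkhd1, Bicc1, Cys1, Pkd2, Kif12, Nphp1 and Glis2 are also on the HNF1B target list. Bicc1, an RNA-binding protein whose loss gives renal cysts, fell from 731 ± 54.2 to 131 ± 12.3 CPM (SD, n = 3 each), a log2 change of -2.48 (SE 0.09, adjusted p = 8.7e-08, edgeR quasi-likelihood F test with Benjamini-Hochberg adjustment). Cys1, the cilium-associated protein cystin, fell by 3.54 on the log2 scale, and Pkd2, a gene of dominant polycystic kidney disease, by 0.69. Bbs1 and Ift88, genes of the ciliary machinery, fell by 0.84 and 0.46. Vhl, the von Hippel-Lindau tumour suppressor gene, rose by 1.05 on the log2 scale (SE 0.10), within a chromosomal window with a median log2 change of 0.82, and Pkd1 rose by 0.26. Without HNF1B_KO replicate 2 only 1 member rose. The median of the list was -0.33. Camera gave an adjusted p of 1.7e-05 for a lower level, and the adjusted p = 0.200 with an estimated correlation.

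Kidney transcription factors also fell more often than they rose. Of 36 listed, 22 were tested, of which 13 fell, 2 rose and 7 did not pass, with the same counts when adjusted over the list alone. Hnf1a, Hnf4a, Pax2, Lhx1, Emx2, Irx1 and Irx2 are also on the HNF1B target list, so the 2 lists are not independent. Tfcp2l1, a regulator of collecting duct cells, fell from 42.2 ± 0.902 to 8.38 ± 0.632 CPM (SD, n = 3 each), a log2 change of -2.33 (SE 0.08, adjusted p = 8.8e-08, edgeR quasi-likelihood F test with Benjamini-Hochberg adjustment). Sall1, a zinc finger factor needed for kidney development, fell by 2.08 on the log2 scale (SE 0.11), and Wt1 by 1.71. Mecom rose from 5.86 ± 0.779 to 12.5 ± 1.3 CPM, and Grhl2, an epithelial transcription factor, rose from 0.218 to 0.621 CPM. Pax8 had a log2 change of -0.19 and an adjusted p of 0.0874 and did not pass. The median of the list was -0.44. Camera gave an adjusted p of 6.1e-05 for a lower level, and the adjusted p = 0.200 with an estimated correlation.

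Markers of nephron segments moved in both directions. Of 30 proximal tubule genes 8 were tested, and 3 rose, 3 fell and 2 did not pass, with the same counts when adjusted over the list alone. Lrp2, the endocytic receptor megalin, fell from 775 ± 58.1 to 277 ± 12.4 CPM (SD, n = 3 each), a log2 change of -1.48 (SE 0.07), whereas its partner Cubn rose by 1.00. The water channel gene Aqp1 rose by 2.43 (SE 0.12), in a chromosomal window with a median of -0.40, and Ass1, an enzyme of arginine synthesis, rose by 2.37 (SE 0.20). Of 32 genes of the distal nephron and collecting duct 11 were tested, and 4 rose, 4 fell and 3 did not pass, again with the same counts over the list alone. Kcnj16 and Cldn19 fell, the latter by 3.44 on the log2 scale. Krt7 rose from 0.667 ± 0.102 to 3.48 ± 1.17 CPM, and Hsd11b2, which inactivates glucocorticoids, rose from 0.202 ± 0.0440 to 0.616 ± 0.154 CPM. The count of risen distal genes was 2 without WT replicate 2 or 3, without any 1 of the HNF1B_KO libraries, and in DESeq2. The distal median was -0.09 without WT replicate 3 and -0.02 and -0.20 without HNF1B_KO replicates 1 and 3. The proximal median was 0.14 without WT replicate 1 and 0.16 and 0.06 without HNF1B_KO replicates 1 and 3. In DESeq2, which tested more genes of both lists, the medians were -0.12 (proximal) and 0.25 (distal). Neither list passed camera, with an adjusted p of 0.545 for the proximal list, median 0.30, and of 0.359 for the distal list, median -0.32.

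Among 22 tested genes of epithelial junctions and polarity, out of 39 listed, 11 fell, 8 rose and 3 did not pass, with the same counts when adjusted over the list alone. Cdh16, described with the HNF1B targets, and the tight junction gene Cldn2 fell. Cldn2 had 2.01 ± 0.466 CPM (SD, n = 3) in WT and 2 counts over the 3 HNF1B_KO libraries, a WT to HNF1B_KO ratio of 106 (95% counting interval 29.0 to 879). Cldn1 had 0 counts in HNF1B_KO against 0.426 CPM in WT, at least 15.1-fold lower. Tjp1, which encodes the junction scaffold ZO-1, fell by 0.45. Pkp3, a desmosomal plakophilin, rose from 1.73 ± 0.170 to 26.6 ± 1.38 CPM, a log2 change of 3.94 (SE 0.11, adjusted p = 3.3e-08, edgeR quasi-likelihood F test with Benjamini-Hochberg adjustment). Its chromosomal window had a median of 0.95. The desmosomal genes Dsp and Jup rose by 2.15 and 0.43. The list had a median log2 change of -0.33, or 0.33 in DESeq2, where 30 members were tested, and did not pass camera (adjusted p = 0.351).

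The list of mesenchymal transition and matrix genes held large changes of opposite sign. Of 40 genes 38 were tested: 17 rose, 10 fell and 11 did not pass, against 18 and 10 when adjusted over the list alone. Lox fell by 8.10 on the log2 scale (SE 0.14), and Mmp2, a matrix metalloprotease that degrades collagen, fell by 4.95. Fn1, the fibronectin gene, rose from 2842 ± 174 to 5065 ± 383 CPM (SD, n = 3 each), and Serpine1, an inhibitor of plasminogen activators, rose from 75.1 to 351 CPM. Fbn1, the fibrillin-1 gene, rose by 2.51 (SE 0.13, adjusted p = 9.4e-07, edgeR quasi-likelihood F test with Benjamini-Hochberg adjustment) in a window with a median of 0.38. An annotated gene on the opposite strand shares 20.1% of the exon bases of Fbn1. The transcription factors of the transition were divided, with Zeb1 at -1.02, Snai1 at -1.13, Zeb2 at 0.39 and Twist2 at 1.71, all past the threshold. The median of the list was 0.23 and its mean -0.02, and camera pointed downwards without passing (adjusted p = 0.941). Without WT replicate 1 the median was 0.15.

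Mitotic genes rose without exception among those that passed. All 32 were tested, of which 20 rose, 0 fell and 12 did not pass, against 22 and 0 when adjusted over the list alone. At an unadjusted p under 0.05, edgeR gave 23 risen and 0 fallen, and DESeq2 and limma voom after adjustment each gave 22 and 0. Tpx2, which nucleates spindle microtubules, rose from 198 ± 40.2 to 330 ± 18.6 CPM (SD, n = 3 each), a log2 change of 0.74 (SE 0.13, adjusted p = 0.00114, edgeR quasi-likelihood F test with Benjamini-Hochberg adjustment). Cyclin B2 (Ccnb2) rose by 0.67 (SE 0.11) and the mitotic kinase gene Cdk1 by 0.74, while Mki67 had a log2 change of -0.05. DNA replication genes showed the same pattern, with 19 risen, 0 fallen and 11 not past the threshold among 30, and the same counts over the list alone. At an unadjusted p under 0.05, edgeR gave 20 risen and 0 fallen, and after adjustment DESeq2 gave 20 and 0 and limma voom 19 and 0. E2f1, a transcription factor of S-phase entry, rose from 26.3 ± 6.41 to 61.3 ± 3.76 CPM, cyclin E1 (Ccne1) rose by 0.77 (SE 0.15), and Pcna by 0.81. The medians of the lists were 0.45 and 0.52.

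Camera gave an adjusted p of 0.00324 for a higher level of the mitotic list and of 0.00250 for the replication list, and for each the adjusted p = 0.628 with an estimated correlation. WT replicate 2 stood apart in both lists. Its mean log2 CPM over the mitotic genes was 6.20, against 6.81 and 6.67 in the other WT libraries and 6.95, 6.94 and 7.13 in HNF1B_KO. For the replication genes it was 5.39, against 6.07 and 5.93 in WT and 6.21, 6.33 and 6.49 in HNF1B_KO. Without that library 18 mitotic genes rose and 1 fell, Ube2c with a log2 change of -0.19 (named because it was the only one), and the median was 0.27. Of the replication genes 18 rose and 0 fell, with a median of 0.34. Without that library camera gave an adjusted p of 0.00541 and 0.00202 for the mitotic and replication lists. Without HNF1B_KO replicate 3 the counts dropped further, to 12 risen and 0 fallen in each list, with an adjusted p of 0.0174 and 0.0146 in camera. Under glmTreat 11 mitotic and 10 replication genes rose, and on unfiltered log2(TPM + 1) 12 of each.

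**Figure D4:**
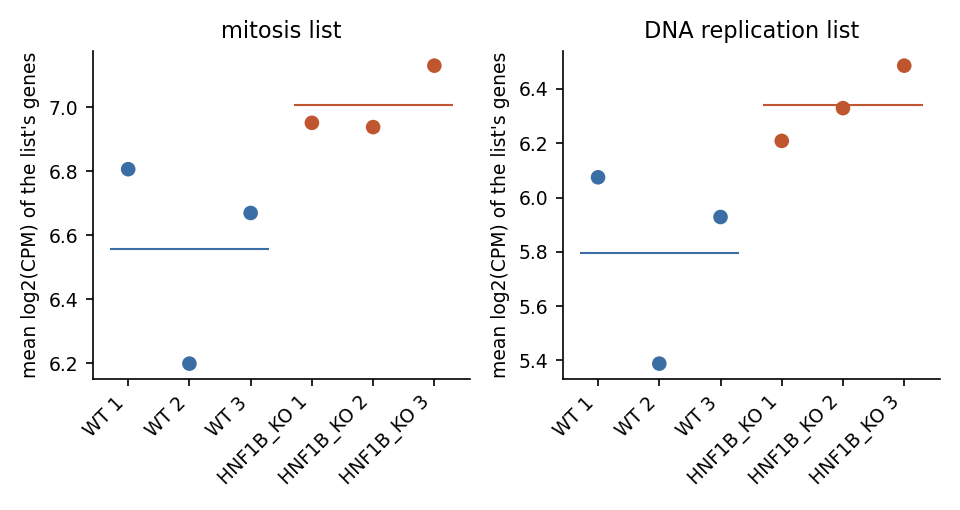
Mean log2 CPM (y axis) over the 32 mitotic and the 30 DNA replication genes in each library (points, 3 WT and 3 HNF1B_KO), with group means as lines and axes that do not start at 0. WT replicate 2 lies lowest in both, at 6.20 and 5.39.

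Cholesterol synthesis genes fell almost throughout. Of 26 genes, all tested, 23 fell, 0 rose and 3 did not pass, with the same counts when adjusted over the list alone, at an unadjusted p under 0.05 in edgeR, and in DESeq2 and limma voom. Dhcr24, the enzyme that reduces the sterol side chain, fell from 14 ± 2.59 to 0.160 ± 0.0423 CPM (SD, n = 3 each), 85.7-fold lower (log2 change -6.42, SE 0.25, adjusted p = 1.7e-07, edgeR quasi-likelihood F test with Benjamini-Hochberg adjustment). Hmgcs1, which makes HMG-CoA, fell from 490 ± 16.2 to 253 ± 7.46 CPM, and Hmgcr, the rate-limiting reductase, fell by 0.52 on the log2 scale. The pathway regulator Srebf2 fell by 0.33. Scap, Ldlr and Dhcr7 did not pass, with log2 changes of 0.10, -0.11 and -0.09. The median of the list was -0.64, camera gave an adjusted p of 9.1e-10 for a lower level, and the adjusted p = 0.235 with an estimated correlation.

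Interferon response genes rose for the most part. Of 29 listed genes 23 were tested, of which 17 rose, 3 fell and 3 did not pass, with the same counts when adjusted over the list alone. Oas1a, an antiviral oligoadenylate synthetase, rose from 0.175 ± 0.0584 to 2.98 ± 0.250 CPM (SD, n = 3 each), a log2 change of 4.05 (SE 0.27, adjusted p = 3.1e-06, edgeR quasi-likelihood F test with Benjamini-Hochberg adjustment). Ifi27 rose from 5.38 ± 1.07 to 19.1 ± 0.525 CPM, and Irf7, a regulator of interferon genes, rose by 1.75 on the log2 scale. The genes that fell were Ifit3, by 2.15 (SE 0.12), Ifit2, by 0.60, and Stat2, by 0.54. Ifit3 and Oas1a, members of multigene families, had fractional counts and so are less certain. The median was 1.22, camera gave an adjusted p of 0.00173 for a higher level, and the adjusted p = 0.235 with an estimated correlation. With only genes of a mean count of at least 50 tested, the adjusted p for the list was 0.0656.

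Genes of canonical WNT signalling rose more often than they fell, but the list did not pass. Of 26 genes 16 were tested, of which 9 rose, 4 fell and 3 did not pass, with the same counts when adjusted over the list alone. Cyclin D1 (Ccnd1) rose from 66.1 ± 13.3 to 494 ± 38.6 CPM (SD, n = 3 each), a log2 change of 2.90 (SE 0.13, adjusted p = 4.3e-07, edgeR quasi-likelihood F test with Benjamini-Hochberg adjustment). It lies in a chromosomal window with a median of 1.2, and 23.4% of its exon bases overlap a gene on the opposite strand. Cd44 rose by 1.23 (SE 0.08), and Axin2, a feedback inhibitor of the pathway, by 1.17. Sfrp1, a secreted WNT antagonist, fell from 83.1 ± 6.22 to 5.30 ± 2.15 CPM, and Lef1, a transcription factor of the pathway, fell by 2.07. The median was 0.47. Camera gave an adjusted p of 0.0663 for a higher level, 0.0111 without WT replicate 1 and 0.0148 without WT replicate 2, in a leave-one-out range of 0.0111 to 0.571. With the replicate number as a block camera gave an adjusted p of 0.0416. Without HNF1B_KO replicate 1, 8 members rose and 7 fell with a median of 0.20. The median was 0.31 without WT replicate 3 or HNF1B_KO replicate 2.

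Notch pathway genes were evenly divided. Of 20 genes 16 were tested: 5 rose, 5 fell and 6 did not pass, against 5 and 6 when adjusted over the list alone. Dtx1, a ubiquitin ligase that regulates Notch, rose from 0.0439 ± 0.0140 to 1.32 ± 0.443 CPM, and the ligand gene Jag2 rose by 1.2 on the log2 scale (SE 0.13). The receptor gene Notch1 fell by 1.38 (SE 0.14) and Jag1 by 0.83. Without HNF1B_KO replicate 2 the count of risen Notch genes was 3. The median of the list was -0.15, or -0.09 without HNF1B_KO replicate 3, and its mean 0.16, and camera pointed downwards without passing (adjusted p = 0.941). Among 25 p53 targets, all tested, 11 rose, 8 fell and 6 did not pass, against 13 and 8 when adjusted over the list alone. The cell cycle inhibitor gene Cdkn1a rose from 3.79 ± 0.201 to 16.1 ± 0.964 CPM (SD, n = 3 each), and Eda2r rose by 2.27 (SE 0.21). Bax, a promoter of apoptosis, fell by 0.39 (SE 0.06). The p53 list had a median of 0.30 and did not pass camera (adjusted p = 0.176).

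Top1, the topoisomerase named with HNF1B in the study's title, did not change detectably. It stood at 167 ± 11.2 CPM in WT and 182 ± 15.4 CPM in HNF1B_KO (SD, n = 3 each), a log2 change of 0.12 (SE 0.08, adjusted p = 0.221, edgeR quasi-likelihood F test with Benjamini-Hochberg adjustment). Of the 8 genes of topoisomerases and their repair enzymes, all tested, 4 rose, 1 fell and 3 did not pass, with the same counts when adjusted over the list alone. Top1mt, the mitochondrial enzyme, rose from 10.9 ± 1.37 to 20.4 ± 0.944 CPM, Top3a rose by 0.35 (SE 0.09), and Tdp2, which repairs topoisomerase 2 adducts, rose by 0.21. Top2b fell by 0.26 (SE 0.06). Top2a, which is also on the mitotic list, rose by 0.47 (SE 0.17, adjusted p = 0.0390, edgeR quasi-likelihood F test with Benjamini-Hochberg adjustment). Top2a no longer passed without HNF1B_KO replicate 1, 2 or 3, with an adjusted p of 0.0571, 0.0618 and 0.128. Without any 1 of these libraries 2 genes of the list rose. Top2a also did not pass in the robust fit, under glmTreat and on unfiltered log2(TPM + 1), nor Top3a under glmTreat, with offsets for effective length and on the TPM scales, nor Top2b under glmTreat. The list had 2 risen genes with offsets for effective length, and 1 risen and 0 fallen under glmTreat. The list had a median of 0.19 and did not pass camera (adjusted p = 0.307).

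Among 31 genes of oxidative phosphorylation, all tested, 12 fell, 1 rose and 18 did not pass, with the same counts when adjusted over the list alone. Sdhb, a subunit of succinate dehydrogenase, fell from 88.8 ± 0.356 to 43.0 ± 3.81 CPM (SD, n = 3 each), a log2 change of -1.05 (SE 0.07). Its partner subunit Sdhc fell by 0.44 (SE 0.06) and Sdha by 0.25. Uqcrq, a subunit of complex III, rose by 0.35 (SE 0.06) but did not pass under glmTreat. There 2 members fell and 0 rose, against 7 and 3 on the TPM scales, and 3 rose when scaled by library totals. The median of the list was -0.09, and it did not pass camera (adjusted p = 0.176).

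Markers of other cell types moved in both directions. Of 7 tested fibroblast markers out of 16, 3 rose, 1 fell and 3 did not pass. Dcn, the matrix proteoglycan decorin, rose from 0.301 ± 0.0301 to 6.31 ± 0.903 CPM (SD, n = 3 each), and Twist2, the most abundant of them, rose from 3.14 ± 0.643 to 10.3 ± 2.09 CPM. A gene on the opposite strand shares 46.5% of the exon bases of Twist2, whose counts were fractional. Col1a2 also rose, to 0.550 CPM, and Pdgfrb fell by 1.33 (SE 0.36). Pdgfrb did not pass in DESeq2, where 4 fibroblast markers rose and 0 fell, on the TPM scales or at an adjusted p under 0.01. Of 5 tested leukocyte markers out of 16, 2 rose, 1 fell and 2 did not pass. Csf1r, the macrophage colony-stimulating factor receptor and the most abundant of them, fell from 26.7 ± 2.10 to 9.15 ± 2.72 CPM. The leukocyte phosphatase Ptprc rose to 0.730 ± 0.177 CPM and the lysozyme gene Lyz2 to 0.362 ± 0.128 CPM. The leukocyte list had a median of -0.17, a mean of 0.59 and an upward camera direction that did not pass (adjusted p = 0.950). Its median was 0.11 without WT replicate 3, and 0.014 and -0.08 without HNF1B_KO replicates 1 and 3. The fibroblast list, at a median of 0.13, did not pass either (adjusted p = 0.0966), though its adjusted p was 0.00960 with only genes of a mean count of at least 50 tested. Its median was below 0 with offsets for effective length (-0.06) and on the log2(TPM + 1) and log2(TPM + 0.1) scales (-0.0037 and -0.01). Leaving out WT replicates 1 and 3 gave -0.0062 and 0.22, and leaving out HNF1B_KO replicates 1 to 3 gave 0.06, -0.02 and 0.34.

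Of 6 tested endothelial markers out of 14, 4 rose, 1 fell and 1 did not pass. Vwf, the von Willebrand factor gene, rose from 0.233 ± 0.0934 to 2.54 ± 0.286 CPM (SD, n = 3 each), and Cdh5 to 0.586 CPM. Flt1, a receptor for vascular endothelial growth factor, rose by 0.66 (SE 0.11), in a window with a median of 0.31. Kdr, the most abundant of them, rose by 0.59 (SE 0.19, adjusted p = 0.0288, edgeR quasi-likelihood F test with Benjamini-Hochberg adjustment), with overlapping groups. Kdr no longer passed without WT replicate 1 or 3 or without HNF1B_KO replicate 1 or 2, with an adjusted p of 0.0592, 0.108, 0.104 and 0.0683, nor under glmTreat or on the TPM scales. Egfl7 had 0.406 ± 0.0534 CPM in WT and 2 counts over the 3 HNF1B_KO libraries, a WT to HNF1B_KO ratio of 21.6 (95% counting interval 5.66 to 184). Of 7 tested podocyte markers out of 10, 4 fell, 2 rose and 1 did not pass. Clic5 fell by 1.40 (SE 0.11), and Npnt, the matrix protein nephronectin, fell by 1.26 (SE 0.13). Podxl, the sialomucin podocalyxin and the most abundant of them, rose from 71.2 ± 7.21 to 121 ± 4.94 CPM, in a window with a median of -0.55. For the 4 lists of other cell types the counts were the same when adjusted over the list alone. The endothelial list had a median of 0.63 and an adjusted p of 0.176 in camera, and the podocyte list a median of -0.97 and an adjusted p of 0.196.

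**Figure D5:**
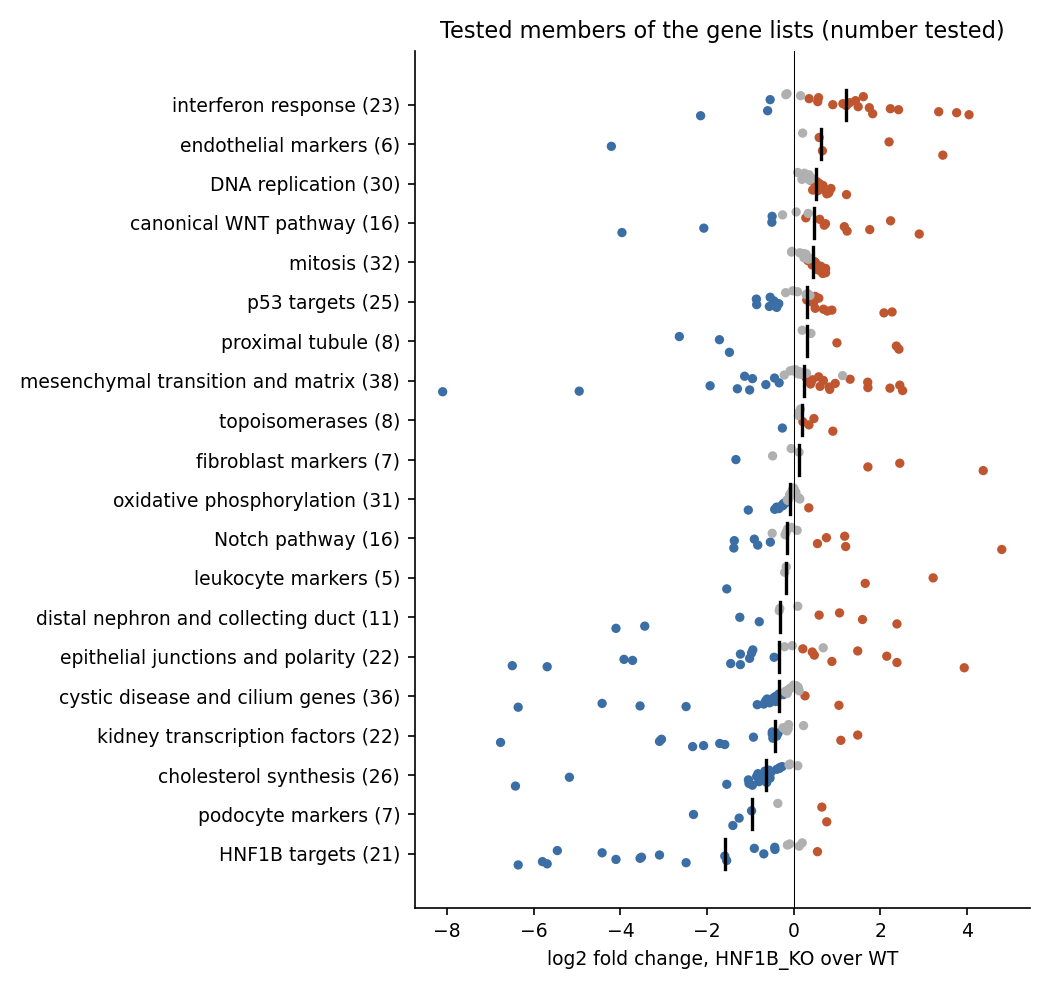
Log2 fold change of HNF1B_KO over WT (x axis) for each tested member (points) of the 20 gene lists (y axis), orange where it rose, blue where it fell and grey where it did not pass, with the median of each list as a black bar. The medians run from -1.59 for HNF1B targets to 1.22 for the interferon response.

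General measures of the libraries were compared between genotypes, with tests that cannot give a p under 0.1 and so cannot show that values were alike. Mitochondrial transcripts made up 2.92% ± 0.320 of counts in WT and 2.77% ± 0.222 in HNF1B_KO (SD, n = 3 each; exact permutation test, two-sided, p = 0.6). Ribosomal protein genes held 4.40% ± 0.0792 and 4.14% ± 0.167 (exact permutation p = 0.2), and the 10 most abundant genes 5.58% ± 0.342 and 5.26% ± 0.201 (exact permutation p = 0.2). More genes were detected in HNF1B_KO, 20167 ± 195 against 19154 ± 137, with every HNF1B_KO library above every WT library, and the exact permutation p = 0.1 is the smallest that 3 against 3 libraries can give. Pairs of replicates of the same genotype differed by more than sampling noise, with a chi-square per degree of freedom of 9.68 to 25.8, against 110 to 161 between genotypes. For the gene lists together, the camera calls that passed at the preset correlation were 7 of 20, and 0 of these 7 passed with an estimated correlation. In fry, which does not compare a list with other genes, the mitotic and replication lists did not pass and the others of these 7 did.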

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

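The trends over GC content and length were tried only after the data had been seen. Of 1602 values of the 70 named genes under alternatives, 1574 kept their direction and their side of the threshold, 28 no longer passed and 0 reversed; the 28 belong to Kdr, Top2a, Top3a, Pdgfrb, Top2b and Uqcrq. The count of changed genes was 4508, with 2274 higher and 2234 lower, under glmTreat, which asks for more than a 1.2-fold change by construction. More genes were higher than lower with library totals (3997 and 3545), on log2(TPM + 1) (3811 and 3095, unfiltered 3628 and 2753) and log2(TPM + 0.1) (3854 and 3099), without a filter (4186 and 3921) and with GC and length trends removed (3973 and 3844). The same held by smaller margins with DESeq2 size factors (3804 and 3743), upper quartile scaling (3783 and 3754) and a mean count of at least 50 (3267 and 3257). Genes changed at least 2-fold numbered 1059 with a mean count of at least 50, where fewer genes are tested, and 933 on log2(TPM + 1) or 943 without a filter, where the pseudocount shrinks changes of low genes. Leave-one-out gave 6392 to 7464 changed genes. With the replicate number as a block 7946 genes changed and with GC and length trends removed as well 8232, against 7580. Whether the numbers pair the libraries cannot be told. Same-numbered libraries deviated together with weak positive correlations of 0.08, 0.11 and 0.16. HNF1B_KO replicate 1 correlated slightly better with WT replicate 2 (0.0924) than with WT replicate 1 (0.0799). The block changed 1 list call, canonical WNT (adjusted p = 0.0416). For that list leave-one-out ran from 0.0111 to 0.571. With a mean count of at least 50 the interferon list gave 0.0656 and the fibroblast list 0.00960. With an estimated correlation the HNF1B target list gave 0.0502, the cystic and the transcription factor lists 0.200, mitosis and replication 0.628, and cholesterol and interferon 0.235. Fry, which does not compare a list with other genes, gave an adjusted p of 0.000235 for HNF1B targets and 0.00047 for cystic genes. It gave 0.000675 for transcription factor and interferon genes, 0.000837 for cholesterol, 0.0858 for mitosis and 0.0767 for replication. Among lists that did not pass camera, fry gave 0.00234 for proximal, 0.0131 for distal and 0.0318 for epithelial and topoisomerase genes. It also gave 0.0266 for WNT, 0.00462 for p53, 0.00313 for oxidative phosphorylation and fibroblast, 0.0139 for endothelial and 0.0135 for podocyte genes. Beyond what the construction of an alternative shows, the cause was not tested. Without a filter the medians of 4 lists that did not pass camera changed sign, proximal to -0.03, distal to 0.10, epithelial to 0.44 and leukocyte to 1.06, and DESeq2, which also tests more genes, turned the first 3, to -0.12, 0.25 and 0.33. Of the lists that passed camera, the added pluripotency list changed sign without a filter, from -1.04 with 4 genes tested to 0.72 with 14. Depth limits folds against 0 counts to a bound. In the simulated data 62% of 1.5-fold changes were recovered, with only 50 of 14417 genes changed at each size. Here 51.9% of the tested genes changed, which makes the adjusted threshold less strict, so that share does not carry over.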

Other observations

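The 6 lists in this part, the removal of GC and length trends, the count of risen genes outside the Zscan4 family and the unfiltered comparison of 2-cell-stage genes were chosen after the results had been seen. Genes of the 2-cell embryo rose in HNF1B_KO. Of 27 tested out of 37 listed, 26 rose, and Arg2, an arginase, fell from 0.451 to 0.0459 CPM. Zscan4c rose from 0.155 to 4.99 CPM and Usp17la, a deubiquitinase gene, from 0.320 to 3.33 CPM. Zfp352, a zinc finger gene, rose from 0.0093 CPM, which is 1 count over the WT libraries together, to 1.64 CPM. Camera gave the list an adjusted p of 9.9e-24 for a higher level (Benjamini-Hochberg over 6 lists), and the adjusted p = 0.0424 with an estimated correlation. The median of the 27 in WT was only 0.0335 CPM. Most of them were therefore kept by the filter only because they were high in HNF1B_KO, and could hardly have fallen. So neither the share that rose nor the camera result is an independent test. Without a filter, 35 listed genes had a median of 0.025 CPM in WT and 1.03 CPM in HNF1B_KO. Of 4 tested pluripotency genes 2 fell, Tfcp2l1 and Klf2, and Trim28 and Tet1 had log2 changes of -0.10 and 0.13 without passing (adjusted p = 0.00644 in camera, and the adjusted p = 0.121 with an estimated correlation). Their median of -1.04 was -0.10, -0.14 and -0.08 without WT replicates 1 to 3 and -0.09 without HNF1B_KO replicate 3, with 1 risen gene each. Without a filter on low counts 14 were tested, 1 rose and 2 fell, and the median changed sign to 0.72.

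Among 30 tested HOX genes, the homeodomain factors of body position, 16 fell and 2 rose. Hoxc13 fell from 6.54 to 0.0373 CPM, Hoxc4 by 1.87 on the log2 scale and Hoxa10 by 1.14. The genes that rose were Hoxb6, at a log2 change of 0.72, and Hoxb5, at 0.40 (camera adjusted p = 9.4e-05, and the adjusted p = 0.421 with an estimated correlation). Hoxc4 and Hoxc13 lie in a block of chromosome 15 from 102.1 to 103.5 Mb whose 39 genes had a median log2 change of -0.76. The Hoxa cluster with Hoxa10 lies in a block of chromosome 6 from 48.63 to 83.16 Mb whose 148 genes had a median of -0.40. Without WT replicate 1 or 3 or HNF1B_KO replicate 1 or 2 only 1 HOX gene rose. Of 30 imprinted genes 14 fell and 8 rose (adjusted p = 0.422). Peg3, a paternally expressed zinc finger gene, fell from 873 to 274 CPM, and Mest from 4.87 to 0.104 CPM. Kcnq1 rose from 0.0605 to 6.52 CPM and Phlda2 from 0.0764 to 1.64 CPM, both inside the shifted block of chromosome 7. The risen genes Tssc4, Nap1l4, Cd81 and Slc22a18 lie in that block too, and only Slc38a4 and Mcts2 rose elsewhere. Within the same block H19 fell and Kcnq1ot1 did not pass. Fatty acid synthesis genes were lower in 9 of 19 with 1 higher, Pnpla3, at a log2 change of 1.44. Scd2, a desaturase, fell by 0.77 (adjusted p = 0.0214 for the list, and the adjusted p = 0.455 with an estimated correlation). Of 5 germline genes 2 rose, Taf7l and Spo11, and 1 fell, Ctcfl, with a median of 0.61, a mean of -0.41 and a downward camera direction that did not pass (adjusted p = 0.762). Without WT replicate 1 the count of risen germline genes was 4, and the median was 1.04 or more without WT replicate 2 or 3 or HNF1B_KO replicate 1. Xist, the RNA that coats the inactive X chromosome, fell from 16.5 ± 6.03 to 0.111 ± 0.0827 CPM (SD, n = 3 each), with fractional counts in at least 1 WT library. The only tested genes annotated on the Y chromosome were Gm20775, Mid1-ps1, Gm47283 and Gm21742, and these 4 did not pass. All have model or pseudogene names, so they do not show whether genes particular to the Y chromosome are expressed.

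The split into WT and HNF1B_KO gave 7580 changed genes, and of the 10 splits of the 6 libraries into 3 and 3 it was the 1 with as many. The highest of the other splits gave 0 in edgeR after Benjamini-Hochberg adjustment and 299 at an unadjusted p under 0.05, where the real split gave 8367. With 10 splits no share under 0.05 can be had. Every other split mixes the genotypes, so their differences add to the spread within groups and few calls could arise. The contrast therefore cannot decide how many genes would be called by chance.

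The genes changed at least 2-fold, 1961 in number, were weighed against copy number and base composition. If shifted segments of many genes were the whole cause, few would differ from their neighbours, but 87.7% (1703 of 1941, 95% exact interval 86.2% to 89.2%) still differed at least 2-fold from the median of the 50 nearest genes. A segment that holds only a minority of those 50 genes hardly moves their median, so small gains or losses were not weighed. The interval treats genes as independent, which neighbours in a shifted segment are not. With GC and length trends removed the count was 1968, or 100.4% of the original, which speaks against those trends as the whole cause. Copy number may still account for part: 1453 of 14444 genes (10.1%) lay in windows with a median of at least 0.3 in size, against at most 0.194% in 100 shuffles, and 22 blocks held at least 20 genes. The strongest spans 139.6 to 145.3 Mb of chromosome 7 (91 genes, median log2 change 0.98), with Ccnd1 and Pkp3, followed by 99.1 to 123.0 Mb of chromosome 14 (48 genes, -0.86) and 112.3 to 117.8 Mb of chromosome 6 (56 genes, 0.77), with Vhl; no DNA was measured, and HNF1B loss and differences between clones stay open and untested.

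A group of 70 genes was expressed in WT at 1 CPM or more and lost in HNF1B_KO, at least 32-fold lower, and 22 of them had 0 counts in all 3 HNF1B_KO libraries; 37 genes were gained. A deletion of many genes would take the nearest expressed neighbour of most of them. That neighbour was lost for 5.71% of the lost genes (4 of 70, with median 0 and highest 8.57% over 1000 shuffles). The 95% exact interval of 1.58% to 13.99% treats the genes as independent, although these 4 form pairs. The pairs are Clec2d with 2310001H17Rik and Lmx1b with C130021I20Rik. For these a deletion of both genes, or shared regulation, stays open, as do deletions of single genes. The same holds for the lost gene Lpcat2, whose nearest expressed neighbour, Mmp2, also fell but just short of 32-fold. A deletion of few genes can leave the nearest neighbour outside it, so the share of lost neighbours cannot decide on small deletions. Reads shared with a near-identical copy would give fractional counts, which were present in 11.4% of the lost genes (8 of 70), against 30.5% of 12311 genes expressed in WT. Why these genes were lost, whether through HNF1B or a difference fixed in a clone, was not tested, and the design cannot separate these.

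The rise of 2-cell-stage genes was weighed against a mixture with embryonic stem cells and against shared reads. Stem cells would bring abundant pluripotency transcripts, but the 16 such genes that WT lacks (under 0.1 CPM) had a median of 0.0141 CPM in HNF1B_KO. That was 1.04% of the median of the 27 tested 2-cell-stage genes (1.35 CPM, against 0.0335 CPM in WT). Nanog was the highest of the 16, at 0.363 CPM against 0.0430 CPM in WT, and was too low to be tested. Testing favours genes that are high in HNF1B_KO. Against 29 unfiltered 2-cell-stage genes with the same limit in WT, the pluripotency median was still only 1.44% (0.0141 against 0.981 CPM). Reads of 1 Zscan4 copy cannot give the rise of the 21 risen genes outside that family, although 23 of the 26 risen genes had fractional counts, so which copies of a family are active stays open; Zfp352, Tmem92 and AF067061 had whole counts in every library. As a hypothesis from these data, a 2-cell-like program may be active in HNF1B_KO cells or in a few of them, which counts per single cell would be needed to decide; neither this nor a link to HNF1B was tested.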
